A study of Homo sapiens with 2 samples.

How the data were processed

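RNA from U937 cells, a human leukemic monocyte lymphoma line, carrying a miR-194-5p vector was measured on 2 2-colour Agilent expression arrays. Per the labels, each array is 1 of 2 biological replicates, the RNA of cells treated with SAHA (vorinostat, an inhibitor of histone deacetylases) at 5 µM for 24 h was labelled with Cy5 (red), and the RNA of the untreated cells was labelled with Cy3 (green). Both arrays had the same dye orientation, so a dye bias cannot be separated from the treatment and no dye term was fitted. The labels do not say whether the untreated RNA of the 2 arrays came from separate cultures, so the spread between the arrays may leave out part of the spread of the controls. Both arrays were on 1 slide and in 1 scan, so there was no batch to fit. The treatment label also names an earlier time point, which was not analysed here.

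Per the file headers, the arrays were scanned on an Agilent scanner and the spot and local background intensities were quantified as median pixel brightness with no normalization. The submitters' processing notes name Agilent Feature Extraction 10.5.1.1. Per the file headers, that program also gave background-subtracted and dye-normalized intensities, and the log10 ratio of red over green, with linear and lowess dye normalization. The deposited scanner files hold a p-value per log10 ratio from the error model of 1 array, which was not used as a test between conditions. The other deposited columns used were flags of 0 or 1 per spot for signal well above background, saturation and outliers. The authors' value table holds a log2 ratio per probe whose scale and centring are not stated in the sources used here. Set against each array's scanner values, its columns followed the log2 ratio of red over green without background subtraction, less a smooth function of the mean log2 signal. Across probes, the correlation with the unsubtracted loess-normalized log2 ratio was 0.981 on replicate 1 and 0.983 on replicate 2, and the direction was therefore taken as red over green. The medians of the deposited log2 columns were −0.0068 and 0.015; how these columns were centred stays unknown.

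The analysis used R 4.3.3 and limma 3.58.1. The median signal of each channel was corrected with the median local background by normexp with an offset of 50. The log2 ratios were then normalized within each array by loess with a span of 0.3, with control spots and outlier spots at weight 0. The design written beforehand named the mean signal of a spot, but the scanner files used here hold the median signal, and that was used in its place. Outlier spots were left out (207 non-control spots on replicate 1 and 216 on replicate 2), no spot was saturated, and spots of a probe were averaged. A probe was kept where at least 1 channel was well above background on both arrays. This left 22835 of 41000 probes. The probe with the highest mean log2 signal represented each gene, which gave 17541 genes and transcripts.

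Gene names came only from the RefSeq accession of each probe, matched without version to a table of RefSeq genes of assembly GRCh38.p14; 26222 probes matched, and the other 14778 kept the name in the scanner file. Among the genes and transcripts tested, 11342 had a gene symbol. The array's annotation was of build hg18, so no coordinates are given. A gene with several kept probes (4042 genes) can hold probes of different transcripts; in 5 of them 1 probe was at least 2-fold higher and another at least 2-fold lower. Probes for near-identical genes, such as those of histones, ribosomal proteins, tubulins, metallothioneins and HLA molecules, can bind each other's RNA.

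The test was limma's linear model with an intercept only, which sets the mean log2 ratio of treated over untreated cells against 0, with empirical Bayes moderation and a Benjamini-Hochberg adjusted p under 0.05, two-sided. It leaves 1 residual degree of freedom per gene. The moderated test had 6.47 degrees of freedom, of which 5.47 came from the spread of all genes. The number of genes with a mean log2 ratio of at least 1 in size and the same sign on both arrays was counted beside it. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 32 lists, and again with the correlation estimated from the data. With 2 arrays the estimated version rests on 1 residual degree of freedom. It could hardly call any list, so a lack of calls there decides little, and the preset correlation stays unchecked. The lists, the design, the naming rule and the alternatives were chosen before the data were examined, except where the text says otherwise. Values written with ± are the mean and SD over the 2 arrays. A standard error range is a list's median plus or minus the standard error of that median, taken from the spread among its members. Members are not independent replicates, so this range does not measure the spread between arrays or cultures.

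The rule for named genes took BCLAF1, which has been described as a target of miR-194-5p. It took the 10 largest increases and the 10 largest decreases among genes with a symbol that passed the test, had the same sign on both arrays and were well above background in both channels. Of each list it took up to 4 members with the largest change among those that passed, or else the brightest member. It also took, in each direction, the 3 genes with the largest lower bound of fold among those not well above background in 1 condition and well above it in the other. Such a bound set the mean log2 signal of the bright channel, after loess and Aquantile normalization, against the higher of the dim probe's own signal and the lowest signal among probes well above background. For all but 8 of the 2657 genes with a bound, and for all 15 named ones, the probe's own signal was the higher, so the bound is the ratio itself, and list medians with genes at their bounds are no separate check. For the named genes it is thus the mean ratio over the arrays, and the ratio on 1 array can be lower. Without dye swaps these bounds are open to dye bias. A few genes that the rule took are not reported here.

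The scripts were tested on simulated arrays with the spread of the real ones, 17541 genes and 20 simulations per setting. With 200 genes changed, an average of 99.0% were recovered at a fold change of 2, 99.98% at 4 and 3.73% at 1.41. In those at 2-fold, between 2.48% and 15.0% of the calls were false (mean 8.67%), and at 4-fold up to 23.4% (mean 9.14%); the degrees of freedom drawn from all genes were estimated between 5.04 and 9.78 at 2-fold. With 12496 genes changed by effects as wide as those observed, 77.5% were recovered and between 1.16% and 2.09% of the calls were false. Camera at an unadjusted threshold of 0.05 called a simulated list of 36 members in 100 of 100 simulations when it was shifted by 0.5 (log2), and in 6 of 100 when it was not shifted. In these simulations genes varied independently and no gene outside the list changed. The rates therefore say nothing about lists whose members vary together, or about a wide response.

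The alternatives were another normexp offset of 16, no background correction, the Feature Extraction log ratio, median centring, no normalization within the array, scale normalization between arrays, no filter on dim probes, a filter on both channels, the mean over all probes of a gene, the deposited value table, an intensity trend or robust moderation, a test against a fold of 1.2, a rank sum test of the lists, and leaving out each replicate. The number of arrays limits the precision of all values.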

Results

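The study measured how gene expression in U937 cells, a human leukemic monocyte lymphoma line, differed after treatment with SAHA (vorinostat), a drug that inhibits histone deacetylases. The cells carried a vector for the microRNA miR-194-5p. Treated cells (5 µM, 24 h) were set against untreated cells of the same kind on 2-colour arrays, with 2 biological replicates per the labels. The median net signal over all probes was 111 in the treated (red) channel and 30.0 in the untreated (green) channel on replicate 1, and 119 and 35.5 on replicate 2. On replicate 1, 58.5% of the 41000 probes were well above background in the treated channel and 46.5% in the untreated channel; on replicate 2 these shares were 55.7% and 44.9%. Cells without the vector were not analysed here, so the values describe SAHA in cells with the vector.

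SAHA was followed by a broad change in expression. The largest decrease was that of ALYREF, an adaptor for mRNA export, at a log2 ratio of −5.36 ± 0.15 (SD, n = 2), and the largest increase was that of the nuclear long noncoding RNA MALAT1 at 4.49 ± 0.15. Of 17541 genes and transcripts tested, 6602 rose and 5894 fell at a Benjamini-Hochberg adjusted p under 0.05 in limma's moderated test, and 5045 did not pass. Of the 11342 with a gene symbol, 4161 rose and 4260 fell. A mean change of at least 2-fold with the same sign on both arrays was seen for 4058, of which 1876 were higher and 2182 lower in treated cells, while a half-difference of that size between the arrays was seen for 6. Across genes, which are not independent replicates, the log2 ratios of the arrays had a correlation of 0.974.

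The direction of a gene rests on where the zero of the ratio was placed. With median centring in place of loess the median of all genes moved by 1.25 (log2), and 22 of the 148 genes named here turned sign. With no normalization within the array it moved by 2.39 and 45 turned. With a shift to the spike-in RNAs, chosen after seeing the data, it moved by −1.53 and 20 turned. Ratios here are therefore relative to the other genes, and shift-corrected median centring, also chosen after seeing the data, is median centring less the shift of all genes; 8 of the named genes turned under it. Under it the medians of the lists of DNA replication (0.033), mitosis (0.094), homologous recombination (0.19), pro-apoptotic genes (0.13), anti-apoptotic genes (−0.57), inflammatory genes (−0.078), MHC class I (0.34), housekeeping genes (0.34), chromatin enzymes (0.0038), neuronal genes (−0.48) and the markers of T and NK cells (−0.23), B cells (−0.72), erythroid cells and megakaryocytes (−0.51) and epithelial cells and fibroblasts (−0.58) also had the opposite sign. Taken as they stand, without allowing for the shift of all genes, 14 of the 32 list medians turned with median centring, 16 with no normalization and 16 with the shift to the spike-in RNAs. Of the lists called below, glycolysis (0.73) and DNA replication (1.29) turned with the first, these (1.86 and 2.42) and MYC and ribosome biogenesis (0.65) and immature myeloid genes (0.59) with the second, and ribosomal proteins (−0.36), histone genes (−0.67) and MHC class II (−1.07) with the third.

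**Figure D1:**
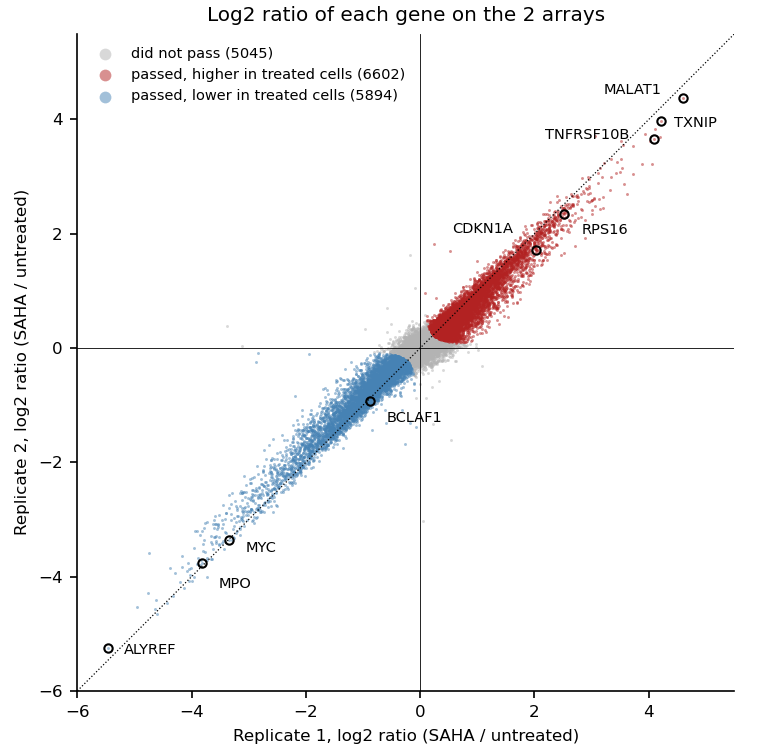
Log2 ratio of SAHA-treated over untreated cells for each of 17541 genes and transcripts on replicate 1 (x axis) and replicate 2 (y axis); colours mark the 6602 that rose and the 5894 that fell, grey the 5045 that did not pass, and the dotted line marks equal values. The points lie along that line, from ALYREF at a mean of −5.36 to MALAT1 at 4.49.

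Among the 10 largest increases measured in both channels were a second nuclear noncoding RNA, NEAT1 (3.84 ± 0.14), and TXNIP, an inhibitor of thioredoxin (4.10 ± 0.17). The kinase gene SGK1 (3.97 ± 0.19), the AP-1 subunit JUN (3.83 ± 0.28), the cyclin G2 gene CCNG2 (3.62 ± 0.13) and the prostaglandin E2 receptor gene PTGER4 (3.57 ± 0.08) also rose. So did TNFRSF10B, a death receptor for TRAIL (3.87 ± 0.30), DACT3, a regulator of Wnt signalling (3.95 ± 0.36), and GRAMD1C (3.63 ± 0.59). After ALYREF, the largest decreases were those of IL18RAP, a subunit of the interleukin-18 receptor (−4.60 ± 0.06), and WDR4, a subunit of a tRNA methyltransferase (−4.53 ± 0.33). The lectin gene CLEC2B (−4.51 ± 0.15), the Rap exchange factor gene RASGRP2 (−4.45 ± 0.02), the pseudouridine synthase gene PUS1 (−4.33 ± 0.01) and the anion transporter gene SLC26A9 (−4.17 ± 0.82) fell as well. CCDC86 (−4.16 ± 0.05), NMI, an interaction partner of STAT proteins (−4.15 ± 0.08), and the AP-1 family member BATF (−4.12 ± 0.25) completed the 10. The largest adjusted p among these 20 genes in limma's test was 1.60e-05. For MALAT1, GRAMD1C and CCNG2 other probes of the gene changed far less, down to log2 ratios of 0.29, 0.45 and 0.25.

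**Figure D2:**
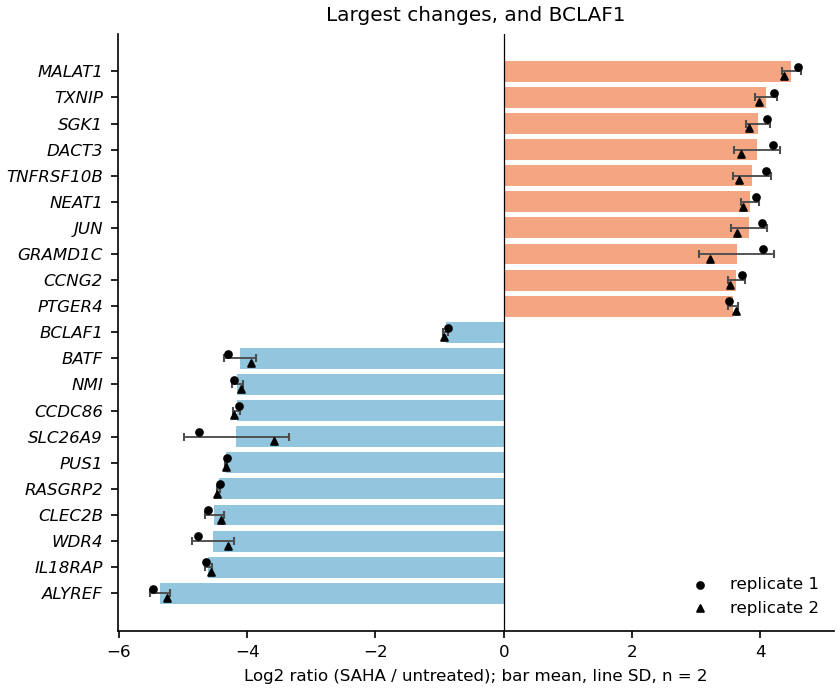
Log2 ratio of SAHA-treated over untreated cells for the 10 largest increases, the 10 largest decreases and BCLAF1; bars are means, lines the SD, circles replicate 1 and triangles replicate 2. The means run from −5.36 for ALYREF to 4.49 for MALAT1, and BCLAF1 lies at −0.90.

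BCLAF1, which encodes a nuclear regulator of transcription and apoptosis and has been described as a target of miR-194-5p, fell by 0.90 on the log2 scale (−0.90 ± 0.04, n = 2; adjusted p = 1.28e-04 in limma's test). That value came from its brightest probe; the other probes read −0.56 ± 0.03 and 0.13 ± 0.04. The mean over probes was −0.44. With median centring in place of loess the brightest probe read 1.00, and −0.26 relative to the shift of all genes; with no normalization it read 2.14. Of the 18 genes in the list of described miR-194-5p targets, 14 were measured, of which 5 rose and 7 fell. SOCS2, a suppressor of cytokine signalling (−2.54 ± 0.35), and the kinase gene AKT2 (−1.23 ± 0.07) fell, while the activin receptor gene ACVR2B (1.06 ± 0.09) and the phosphatase gene PTPN12 (1.05 ± 0.20) rose. The list as a whole was not called by camera (adjusted p = 0.663; adjusted p = 0.905 with an estimated correlation).

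Relative to the other genes, the lists of genes for making ribosomes and of genes for the proteins of the ribosome went opposite ways. Of 33 measured members of the MYC and ribosome biogenesis list, 31 fell and 1 rose, with a median log2 ratio of −2.20. MYC, the transcription factor itself, fell to −3.35 ± 0.01, and the assembly factors RRS1 (−3.06 ± 0.08), LYAR (−2.91 ± 0.09) and PPAN (−2.85 ± 0.44) fell with it. All 36 members of the ribosomal protein list rose, with a median of 1.18, led by RPS16 (2.44 ± 0.12), RPS23 (2.33 ± 0.01), RPS10 (2.16 ± 0.14) and RPS19 (2.11 ± 0.03). Camera called the first list lower (adjusted p = 2.41e-11) and the second higher (adjusted p = 5.65e-10); with an estimated correlation both had an adjusted p = 0.905. With the Feature Extraction log ratio the median of the ribosomal protein list was 0.54, 24 members rose, none fell, and 7 that rose with loess had a ratio under 0. Both lists were called in 14 of 15 other settings, all except the estimated correlation; camera sets a list against the other genes, and shifted to the spike-in RNAs both medians were below 0 (−3.73 and −0.36, with 20 ribosomal protein members falling and 9 rising). Ribosomal protein probes are bright, and the 500 brightest genes had a median log2 ratio of 0.51, against 0.06 for all genes. Ribosomal protein genes were not left out of these 500, so that median may partly reflect them. The next 1500 genes by signal had a median of −0.17.

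Genes of the cell cycle moved in both directions. Of 19 measured members of the list of CDK inhibitors and growth arrest, 12 rose and 5 fell. Besides TXNIP, the antiproliferative genes BTG1 (3.23 ± 0.02) and BTG2 (2.54 ± 0.24) and the stress gene SESN1 (2.23 ± 0.01) rose. CDKN1A, which encodes the CDK inhibitor p21 and is named here after its value was seen, rose to 1.87 ± 0.21. The list missed the camera threshold (adjusted p = 0.0584; adjusted p = 0.905 with an estimated correlation). Of 42 genes for DNA replication and the G1/S step, 25 fell and 9 rose, with a median of −0.41. TYMS, the thymidylate synthase gene, fell most (−3.48 ± 0.07), followed by the uracil glycosylase gene UNG (−1.80 ± 0.45), the helicase gene MCM7 (−1.75 ± 0.06) and E2F1 (−1.45 ± 0.13). Camera called this list lower (adjusted p = 0.00828; adjusted p = 0.905 with an estimated correlation). It was called in 9 of 15 other settings (adjusted p from 3.85e-04 to 0.905). The call, at a median of −0.41 (standard error range −0.57 to −0.24), ended when both channels had to be well above background (adjusted p = 0.0706), although the median there was −0.40 (−0.57 to −0.23). It also ended when shifted to the spike-in RNAs (adjusted p = 0.0629), where the median was −1.94 and all genes moved by −1.53. The median turned to 1.29 with median centring, to 2.42 with no normalization and to 0.033 relative to the shift of all genes, with no call (adjusted p = 0.843, 0.886 and 0.505). Of 42 mitotic genes, 24 fell and 12 rose. FOXM1 (−1.71 ± 0.22), PLK1 (−1.54 ± 0.11) and CENPM (−1.41 ± 0.26) fell, while CDK1, the mitotic kinase gene, rose (1.57 ± 0.02); the list was not called (adjusted p = 0.111; adjusted p = 0.905 with an estimated correlation). Among 32 genes of homologous recombination and Fanconi repair, 11 rose and 13 fell. RBBP8 (−1.52 ± 0.12) and RAD54L (−1.15 ± 0.14) fell and EXO1 rose (0.89 ± 0.00), with no call of the list (adjusted p = 0.897).

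Regulators of cell death also split. Of 26 measured pro-apoptotic genes and death receptors, 9 rose and 12 fell. TNFRSF10B and the BH3-only gene BMF (2.09 ± 0.42) rose, whereas BID (−2.32 ± 0.05) and BAX (−2.30 ± 0.08), which act at the mitochondrial membrane, fell. Other probes read 1.11 for TNFRSF10B, and −0.34 and 0.14 for BAX. Of 15 anti-apoptotic genes, 7 rose and 6 fell: the inhibitor of apoptosis genes BIRC3 (2.10 ± 0.04) and BIRC2 (1.64 ± 0.05) and the BCL2 relative MCL1 (1.80 ± 0.48) rose and AVEN fell (−3.58 ± 0.30). Neither list was called by camera (adjusted p = 0.784 and 0.899; adjusted p = 0.924 for both with an estimated correlation). The anti-apoptotic list had a median of 0.08 and a mean of −0.14, and camera's direction for it was down.

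Members of the list of immature myeloid and primary granule genes were mostly lower. Of 19 measured, 14 fell and 5 rose, with a median of −0.87. The granule protease gene CTSG (−3.87 ± 0.19) and the myeloperoxidase gene MPO (−3.80 ± 0.04) fell most, followed by the myeloid transcription factor gene CEBPE (−2.75 ± 0.25) and the adaptor gene PRAM1 (−2.72 ± 0.17). Camera called the list lower (adjusted p = 0.0197; adjusted p = 0.905 with an estimated correlation). It was called in 11 of 15 other settings (adjusted p from 1.01e-12 to 0.905). The call ended with both channels well above background (16 members, adjusted p = 0.184), with shift-corrected median centring (adjusted p = 0.357) and when shifted to the spike-in RNAs (adjusted p = 0.338, median −2.40, where all genes moved by −1.53). The decrease was not smaller by its median, at −1.46 (standard error range −2.01 to −0.90) and −1.80 (−2.28 to −1.33) in the first 2 of these, against −0.87 (−1.34 to −0.40) with loess. Markers of mature monocytes and macrophages showed no common direction: of 36 measured, 16 rose and 15 fell. EGR2 rose by a mean of 4.76-fold from below background. SIRPA (−2.72 ± 0.45), CYBB (−2.29 ± 0.37) and the integrin gene ITGB2 (−1.80 ± 0.02) fell. Camera did not call the list (adjusted p = 0.899, and adjusted p = 0.924 with an estimated correlation).

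Genes of antigen presentation to CD4 T cells were higher. Of 15 measured genes in the MHC class II list, 11 rose and 1 fell, with a median of 0.46. The peptide-exchange genes HLA-DMB (2.87 ± 0.37) and HLA-DMA (2.15 ± 0.17), HLA-DPA1 (2.27 ± 0.06), whose untreated signal was above background on 1 array, and the lysosomal thiol reductase gene IFI30 (1.62 ± 0.09) rose most. Camera called the list higher (adjusted p = 0.0165; adjusted p = 0.905 with an estimated correlation). It was called in 10 of 15 other settings (adjusted p from 1.44e-05 to 0.905). The call ended with both channels well above background (adjusted p = 0.140), where 8 members were left and the median was 0.87 (standard error range 0.28 to 1.47), against 0.46 (0.11 to 0.81) with loess. It also ended with median centring (adjusted p = 0.0957), with no normalization (adjusted p = 0.581) and with shift-corrected median centring (adjusted p = 0.357), where the median was 0.26 (−0.22 to 0.75) and 5 members that rose had a ratio under 0. In the MHC class I list, 4 of 18 rose and 8 fell. B2M, the light chain, rose (2.56 ± 0.05), while the immunoproteasome genes PSMB10 (−3.71 ± 0.03) and PSMB8 (−2.32 ± 0.06) and the chaperone gene CALR (−1.68 ± 0.22) fell (list adjusted p = 0.455; adjusted p = 0.905 with an estimated correlation). Interferon-stimulated genes were split evenly, with 11 of 35 higher and 11 lower: IFIT1 (2.59 ± 0.10) and CXCL10 (2.49 ± 0.23) rose and IFITM2 (−2.50 ± 0.09) and USP18 (−2.24 ± 0.05) fell. That list had a median of −0.06, a mean of 0.08 and no call (adjusted p = 0.900; adjusted p = 0.924 with an estimated correlation). Of 25 inflammatory genes, 16 rose and 6 fell. IL18 (2.18 ± 0.11) and the NF-κB inhibitor gene TNFAIP3 (2.14 ± 0.14) rose, CCL4 rose by a mean of 2.76-fold from below background, and OSM fell (−1.52 ± 0.30). The list was not called (adjusted p = 0.111; adjusted p = 0.905 with an estimated correlation).

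Histone genes were higher as a list, with 20 of 32 measured members rising, 5 falling and a median of 0.86. Among those that rose were the linker histone gene H1-2 (2.49 ± 0.05), H4C8 (1.61 ± 0.46) and the replacement histone gene H3-3B (1.53 ± 0.04). Camera called the list higher (adjusted p = 0.0165; adjusted p = 0.905 with an estimated correlation). It was called in 11 of 15 other settings (adjusted p from 6.83e-05 to 0.905). The call ended with the Feature Extraction log ratio (adjusted p = 0.0985), the deposited value table (adjusted p = 0.0501) and no normalization (adjusted p = 0.0790). The medians in the first 2 were 1.04 (standard error range 0.78 to 1.30) and 0.91 (0.68 to 1.14), against 0.86 (0.66 to 1.06) with loess, and the moderated t of all genes was more widely spread, with an SD of 22.3 and 12.6 against 9.53. With no normalization the median was 3.46 (3.20 to 3.71), where all genes moved by 2.39. Among 41 genes of histone deacetylases, acetyltransferases and methyltransferases, 13 rose and 20 fell. UHRF1, a partner of DNA methylation (−3.10 ± 0.10), the deacetylase gene HDAC7 (−2.12 ± 0.14) and the acetyltransferase gene KAT2A (−1.93 ± 0.06) fell and the coactivator gene NCOA3 rose (2.35 ± 0.14), with no call (adjusted p = 0.223; adjusted p = 0.905 with an estimated correlation). Of 11 measured members of the bromodomain and P-TEFb list, which also holds SERTAD genes that are neither, 3 rose and 2 fell. SERTAD2 (0.98 ± 0.08), HEXIM2 (0.89 ± 0.22) and BRD3 (0.89 ± 0.03) rose and BRD2 fell (−0.65 ± 0.27), although BRD2 read 0.23 with shift-corrected median centring; the list was not called (adjusted p = 0.891).

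Glycolytic genes were lower, with 15 of 22 falling, 4 rising and a median of −0.90. The enolase gene ENO1 (−2.80 ± 0.12), PFKP (−2.32 ± 0.11), GPI (−2.26 ± 0.03) and the hexokinase gene HK2 (−2.13 ± 0.04) fell most. Camera called the list lower (adjusted p = 0.00828; adjusted p = 0.905 with an estimated correlation). It was called in 10 of 15 other settings (adjusted p from 3.85e-04 to 0.905). The call ended with median centring, as it stands (adjusted p = 0.320) and relative to the shift of all genes (adjusted p = 0.495), where the medians were 0.73 (standard error range 0.47 to 0.99) and −0.53 (−0.79 to −0.27), against −0.90 (−1.20 to −0.61) with loess. It also ended with no normalization (adjusted p = 0.624) and when shifted to the spike-in RNAs (adjusted p = 0.145). The medians there were 1.86 and −2.44, where all genes moved by 2.39 and −1.53. Oxidative phosphorylation genes had no common direction with loess, with 15 of 36 higher and 12 lower. NDUFB5 (1.80 ± 0.03) and NDUFA2 (1.67 ± 0.06) rose and CYC1 (−1.55 ± 0.00) and NDUFS3 (−1.44 ± 0.04) fell. Camera did not call the list (adjusted p = 0.897, and adjusted p = 0.924 with an estimated correlation). It called the list higher with median centring, as it stands (median 2.05, adjusted p = 6.83e-05) and relative to the shift of all genes (0.79, 6.74e-05). With no normalization it was also called higher (median 3.18, adjusted p = 0.0135). Of 28 lysosomal genes, 16 rose and 9 fell, led by GM2A (2.32 ± 0.40), NEU1 (2.10 ± 0.02), NPC2 (2.06 ± 0.25) and LIPA (1.68 ± 0.05). With loess camera did not call the list (adjusted p = 0.223, and adjusted p = 0.905 with an estimated correlation). It called the list higher in 4 of 15 other settings, among them shift-corrected median centring (median 1.13, adjusted p = 0.00578) and no filter on dim probes (0.28, 0.0413). Of 24 genes of cholesterol synthesis and uptake, 9 rose and 8 fell; INSIG1 (1.98 ± 0.09), STARD4 (1.92 ± 0.37) and IDI1 (1.33 ± 0.04) rose and PMVK fell (−1.14 ± 0.05), with no call (adjusted p = 0.910).

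Stress genes moved in both directions, and none of their 3 lists was called with loess. In the list of the unfolded protein response and amino acid stress, 15 of 29 fell and 6 rose. The serine synthesis gene PSAT1 (−2.99 ± 0.15) and TRIB3 (−2.89 ± 0.10) fell, while DDIT3 (2.48 ± 0.33) and DDIT4 (2.19 ± 0.10) rose; the list narrowly missed the camera threshold (adjusted p = 0.0534; adjusted p = 0.905 with an estimated correlation). Of 20 heat shock and chaperone genes, 12 fell and 7 rose, with HSPH1 (−2.68 ± 0.11), HSPE1 (−2.63 ± 0.09), HSP90AA1 (−2.03 ± 0.01) and the regulator HSF1 (−1.74 ± 0.02) all lower (list adjusted p = 0.139; adjusted p = 0.905 with an estimated correlation). Among 27 metallothionein and oxidative stress genes, 15 rose and 8 fell: the ferritin gene FTH1 (2.26 ± 0.06) and GCLC (1.74 ± 0.13) rose and GPX1 (−1.97 ± 0.03) and MT1M (−1.41 ± 0.36) fell (list adjusted p = 0.223; adjusted p = 0.905 with an estimated correlation). Camera called the unfolded protein response list lower in 5 of 15 other settings. It called the metallothionein list higher with median centring, as it stands (median 2.15, adjusted p = 2.45e-04) and relative to the shift of all genes (0.89, 7.87e-05). Of 17 cytoskeleton genes, 4 rose and 10 fell. TUBA1B (−2.07 ± 0.05), FLNA (−2.02 ± 0.26) and TUBA1A (−1.58 ± 0.01) fell and TUBB2A rose (1.85 ± 0.02), but its other probe read −0.56 and its Feature Extraction log2 ratio was −1.05 (list adjusted p = 0.223; adjusted p = 0.905 with an estimated correlation).

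**Figure D3:**
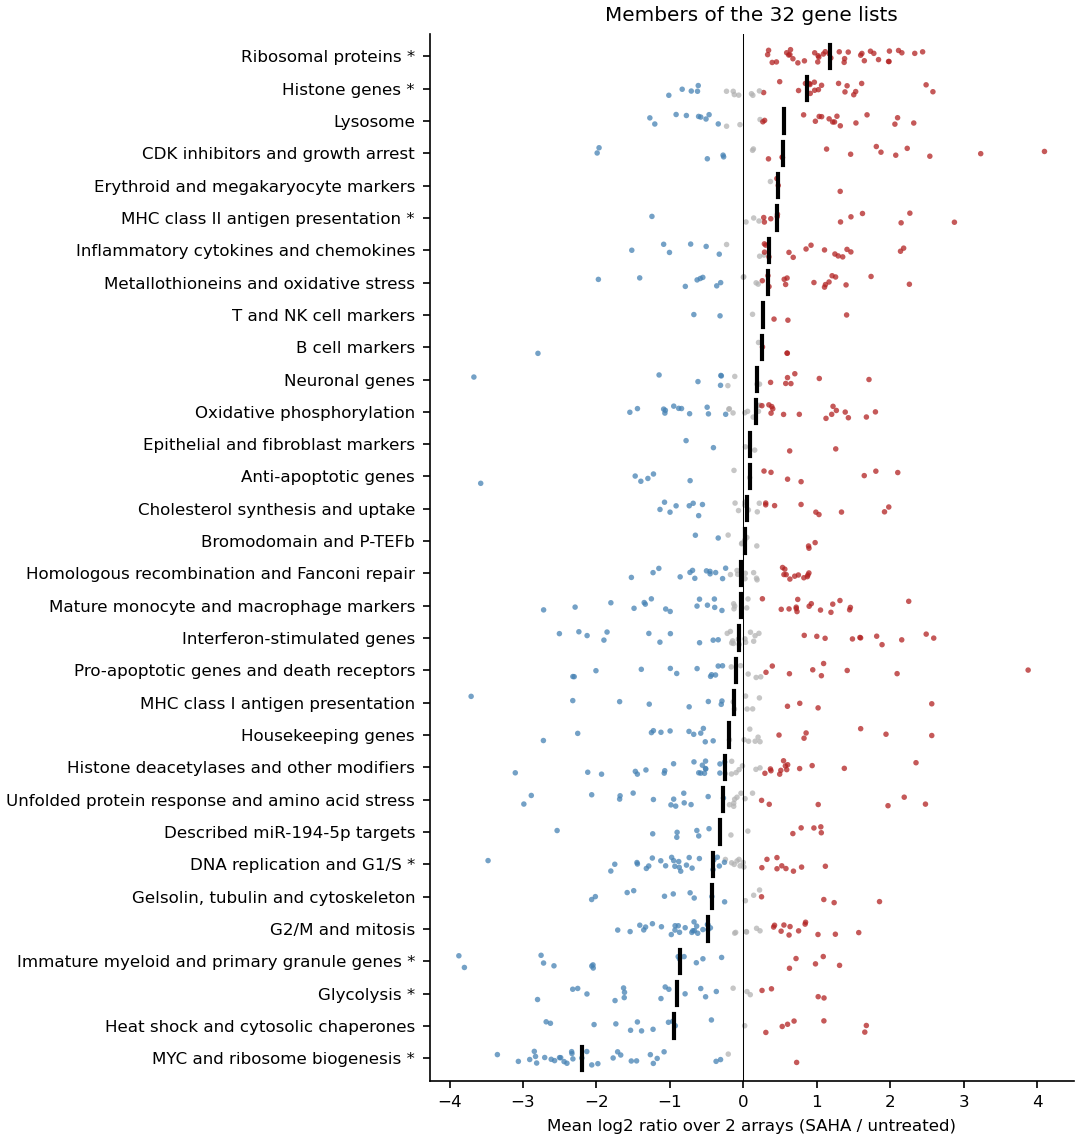
Mean log2 ratio of SAHA-treated over untreated cells for the measured members of 32 gene lists; points are genes (red rose, blue fell, grey did not pass), black bars are list medians, the vertical line marks 0, and an asterisk marks the 7 lists called by camera at the preset correlation. The medians run from −2.20 for MYC and ribosome biogenesis to 1.18 for ribosomal proteins.

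Markers of other cell types were mostly not well above background. Of 22 T and NK cell markers 6 were measured, of which 3 rose and 2 fell. GZMB (1.40 ± 0.17) rose, and CD2 and IL7R rose by means of 1.52-fold and 1.33-fold from below background. CD4, which monocytes also express, fell (−0.67 ± 0.04). Of the B cell markers 5 were measured, and 3 rose and 1 fell. CD79A fell (−2.80 ± 0.19), and FCRLA (mean 1.51-fold) and JCHAIN rose from below background. JCHAIN did not pass in several other settings, among them normexp at an offset of 16, scale normalization, no filter on dim probes, the mean over probes and an intensity trend. Of the erythroid and megakaryocyte markers 4 were measured and 3 rose, GP9 to 1.32 ± 0.27, and HBB and PPBP by means of 1.39-fold and 1.37-fold from below background. Of 6 epithelial and fibroblast markers KRT18 (1.26 ± 0.48) and FN1 (mean 1.55-fold, from below background) rose and KRT8 (−0.78 ± 0.31) and THY1 (−0.41 ± 0.16) fell. Of 17 measured neuronal genes 7 rose and 6 fell, among them DPYSL3 (1.71 ± 0.38), whose untreated signal was above background on 1 array, CHGB (1.03 ± 0.32), STMN3 (−1.15 ± 0.01) and BEX1 (−3.67 ± 0.04). None of these lists was called by camera (adjusted p from 0.194 to 0.924). The neuronal list had a median of 0.18 and a mean of −0.04, and the B cell list a median of 0.26 and a mean of −0.23, while camera's direction was up for both. With shift-corrected median centring the ratios of CD2, IL7R, FCRLA, JCHAIN, HBB, PPBP and FN1 were below 0. In limma's test against a fold of 1.2, HBB (adjusted p = 0.0896), PPBP (0.0688), IL7R (0.148), THY1 (0.163) and JCHAIN (0.733) did not pass.

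Genes often used as references moved in both directions. Of 25 housekeeping genes, 6 rose, 12 fell and 7 did not pass: B2M (2.56 ± 0.05) and VPS29 (1.94 ± 0.10) rose and the actin gene ACTB (−2.72 ± 0.08) and GPI (−2.26 ± 0.03) fell (list adjusted p = 0.455; adjusted p = 0.905 with an estimated correlation). In untreated cells 1309 genes with a symbol were not well above background on either array but were well above it in treated cells, and 64 showed the opposite, in a design where the untreated channel was the dimmer. The largest bounds, each the mean ratio over the arrays, were those of SPP1 (osteopontin, 10.48-fold higher), SERPINI1 (10.1-fold) and SELENOP (8.95-fold). In the other direction they were those of JCAD (3.48-fold lower), NAT8L (3.47-fold) and KASH5 (2.78-fold).

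Adjusted over the list alone, the numbers of members that rose and fell were the same as over all genes in 27 of the 32 lists. In the others they were 9 and 26 for DNA replication, 10 and 12 for pro-apoptotic genes, 17 and 10 for the lysosome, 11 and 10 for interferon-stimulated genes and 5 and 10 for the cytoskeleton. Of the 7 lists called by camera (3 higher, 4 lower), none was called with an estimated correlation, where the smallest unadjusted p was 0.169 and 0 of 32 lists had an unadjusted p under 0.05. That version rests on 1 residual degree of freedom and could hardly call any list, so it neither backs nor refutes the 7 calls. Probes of a gene often differed: of the 48 named genes with several probes, 25 had a probe at least 2-fold from the brightest. Besides those given above, the farthest probes read 0.39 for CDKN1A, 0.58 for GM2A, 0.26 for HLA-DPA1, 0.42 for MCL1, 0.58 for NCOA3, 2.63 for NEAT1, 1.96 for PTGER4, 0.59 for RPS10 and 0.28 for TNFAIP3. They read −0.94 for ACTB, −1.91 for CCDC86, −0.15 for HK2, −0.80 for HSP90AA1, −1.06 for PPAN, −0.32 for SIRPA, −0.47 for SOCS2, −1.73 for UHRF1 and −1.66 for WDR4. Replicates shared 1 dye orientation, so any dye bias of a probe is part of its ratio, and the ratios are relative to the other genes on the array.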

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

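The tests of the spike-in pattern were chosen after the offset had been seen. Control RNAs of known ratio, added to the labelling reactions and used only for the shift to the spike-in RNAs, read above their expected ratio in the red (treated) channel: the intercept of observed on expected log2 ratio, per the file headers, was 1.55 on replicate 1 and 1.52 on replicate 2, or 2.93-fold and 2.86-fold. These spots lie outside the main measurement, and they stand out because the offset is well above 0. The slopes were 0.884 and 0.871 and the correlations 0.974 and 0.973, so the spike-in RNAs kept their order and were not exchanged between the reactions. Because ratios were scaled on sample RNA, a candidate explanation is less mRNA per unit of total RNA in treated cells, which needs an offset above 0 on both arrays; the lower of the offsets was 1.52. Unequal amounts of spike-in mix in the 2 reactions would give the same pattern (mean offset 1.53), so these explanations cannot be told apart without a measure of the amount of RNA and of spike-in per reaction, and the labels used here give neither.

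The second pattern weighed is the breadth of the response itself, for which both tests were planned before the result was seen. With 1 dye orientation, a bias of single probes for a dye could pass as a treatment effect. Of 1160 named genes with a change of at least 2-fold that passed the test and had another probe, the second-brightest probe had the same sign in 92.5% (exact 95% interval 90.8% to 93.9%), where chance would give about 50%; this argues against probe-specific dye bias as the main source of these calls. The dependence of the ratio on signal stays open: the lowest share of the 4058 genes that kept their sign under 3 other scalings was 76.2%, with median centring, and the other scalings, the Feature Extraction log ratio and the deposited table, kept 99.9% and 100%. Median centring moved the median of all tested genes by 1.25 (log2), and relative to that shift 99.98% kept their sign. Genes chosen for a change of at least 2-fold turn only under a large change of scale, so this share says little about signal. Relative to the shift, 3290 of the 4058 stayed changed at least 2-fold. Both the place of the zero and the dependence on signal thus stay open.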

How the results depend on the processing

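The shift to the spike-in RNAs and the shift-corrected median centring were chosen after seeing the data; all other settings were planned. Against 12496 with loess, between 8666 (test against a fold of 1.2) and 17223 (no normalization) genes passed across settings. Scaling changed the split: 52.8% of calls were higher with loess, 91.8% with median centring, 99.4% with no normalization within the array, 39.5% with shift-corrected median centring and 2.67% when shifted to the spike-in RNAs. These settings moved the median of all genes by 1.25, 2.39, −0.0036 and −1.53 (log2), so a shift of the median does not account for the split with shift-corrected median centring. The calls shared with loess were 7424, 6711, 9410 and 6344 of 12496 in these settings. The number changed at least 2-fold, 4058, became 8164 with the Feature Extraction log ratio, 8841 with median centring, 15798 with no normalization, 7172 with shift-corrected median centring (3290 shared with loess) and 13534 when shifted to the spike-in RNAs. It ranged from 3650 to 4615 when 1 replicate was left out; the array left has no residual degrees of freedom and so no test. The number of lists called, 7, became 4 with no normalization, 12 with no filter on dim probes, 4 with both channels above background and 0 with an estimated correlation. The lists of MYC and ribosome biogenesis and of ribosomal proteins were called in 14 of 15 settings run per list, all except the estimated correlation. Of the lists not called with loess, CDK inhibitors and the unfolded protein response were called in 5 of 15 settings, lysosome in 4, inflammatory genes and oxidative phosphorylation in 3, metallothioneins in 2, and mitosis, interferon-stimulated genes and cytoskeleton in 1. The cause was not tested, except that the settings without loess keep the trend of the ratio with signal and a filter on both channels tests fewer genes.

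Some directions turned. With the Feature Extraction log ratio TUBB2A read −1.05. With median centring 22 of 148 named genes turned, with values of 0.74 for AKT2, 1.00 for BCLAF1, 1.49 for BRD2, 0.45 for CALR, 1.07 for CD4, 0.21 for CYC1, 0.16 for E2F1, 0.29 for GPX1, 0.28 for HSF1, 0.024 for HSP90AA1, 0.033 for ITGB2, 0.41 for KRT8, 0.35 for MCM7, 0.50 for NDUFS3, 0.27 for PLK1, 0.61 for PMVK, 0.63 for RAD54L, 0.18 for RBBP8, 0.78 for STMN3, 0.94 for THY1, 0.40 for TUBA1A and 0.37 for TUBA1B, and the DNA replication list had a median of 1.29. With no normalization 45 turned, with values of 0.86 for ACTB, 1.87 for AKT2, 0.64 for BAX, 2.14 for BCLAF1, 0.72 for BID, 2.62 for BRD2, 1.58 for CALR, 2.20 for CD4, 1.00 for CENPM, 1.34 for CYC1, 1.29 for E2F1, 0.45 for ENO1, 0.41 for FLNA, 0.73 for FOXM1, 0.99 for GPI, 1.42 for GPX1, 0.66 for HDAC7, 0.88 for HK2, 1.42 for HSF1, 1.16 for HSP90AA1, 0.73 for HSPE1, 0.46 for HSPH1, 0.35 for IFITM2, 1.17 for ITGB2, 1.05 for KAT2A, 1.54 for KRT8, 0.058 for LYAR, 1.49 for MCM7, 0.44 for MT1M, 1.63 for NDUFS3, 0.43 for OSM, 0.57 for PFKP, 1.40 for PLK1, 1.74 for PMVK, 0.12 for PRAM1, 0.45 for PSMB8, 1.76 for RAD54L, 1.31 for RBBP8, 1.91 for STMN3, 2.07 for THY1, 0.34 for TRIB3, 1.53 for TUBA1A, 1.50 for TUBA1B, 0.053 for UNG and 0.36 for USP18, and the DNA replication list had a median of 2.42. Shifted to the spike-in RNAs 20 turned, with values of −0.47 for ACVR2B, −0.65 for BRD3, −0.071 for CCL4, −0.93 for CD2, −0.50 for CHGB, −0.64 for EXO1, −0.94 for FCRLA, −0.90 for FN1, −0.22 for GP9, −0.13 for GZMB, −0.0059 for H3-3B, −1.06 for HBB, −0.64 for HEXIM2, −0.20 for IDI1, −1.12 for IL7R, −1.27 for JCHAIN, −0.28 for KRT18, −1.08 for PPBP, −0.48 for PTPN12 and −0.56 for SERTAD2. That shift used the intercepts in the file headers (1.55 and 1.52), while the loess-normalized spike-in spots had mean log2 ratios of 1.43 and 1.37. The sign of values near 0, such as those of H3-3B and CCL4, may rest on this choice. In these 3 settings 14, 16 and 16 of the 32 list medians turned as they stand, and 7 did with the Feature Extraction log ratio and 5 with both channels above background, all of lists that were not called with loess in these last 2. With shift-corrected median centring 8 turned, with values of 0.23 for BRD2, −0.18 for CD2, −0.22 for FCRLA, −0.18 for FN1, −0.59 for HBB, −0.26 for IL7R, −0.97 for JCHAIN and −0.58 for PPBP, and the DNA replication list had a median of 0.033. In these settings 6, 11, 9 and 1 further named genes no longer passed. Leaving out saturated spots changes nothing, as none was saturated, and the mean in place of the median of pixels was not run because the files used hold the median. The weaker green signal over background (median net signal 30.0 and 35.5, against 111 and 119 in red) limits ratios of genes low in untreated cells. Each array holds both conditions, so the test of its log2 ratio already compares them within the array, and no separate paired analysis was run. Whether the treated and untreated cultures were themselves paired is not in the labels.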

Other observations

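The gene groups of this part and their tests, and the tests on ribosomal mRNAs other than the one on bright spots, were chosen after the table of all genes was seen, and PUS1 and WDR4 in the first group had been named for their large decrease. Genes in a list of enzymes that modify tRNA were mostly lower in treated cells. Of 33 measured, 26 fell and 6 rose, with a median log2 ratio of −1.13. The list holds 7 of the 15 measured genes with the TRMT prefix, of which 5 fell and 1 rose; of the 8 left out, 1 fell, 2 rose and 5 did not pass, and the 15 as a family were not called (median 0.05, adjusted p = 0.805). With all 15 in the list, 27 of 41 fell and 8 rose, with a median of −0.93 (camera p = 2.00e-04, not adjusted, and p = 0.311 with an estimated correlation). Without PUS1 and WDR4, 24 of 31 fell and 6 rose (median −1.11). Camera gave p = 1.96e-05 there, not adjusted, and p = 0.389 with an estimated correlation. WDR4 (−4.53 ± 0.33) and its catalytic partner METTL1 (−3.33 ± 0.35), which methylate guanosine in tRNA, fell together, as did the pseudouridine synthase genes PUS1 (−4.33 ± 0.01) and PUS7 (−3.77 ± 0.09); the farthest probes of WDR4, METTL1 and PUS7 read −1.66, −2.08 and −1.37. Of 19 genes for cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 17 fell and 1 rose (median −0.77), led by VARS1 (−2.80 ± 0.41) and YARS1 (−2.47 ± 0.35). With shift-corrected median centring 11 of these fell and 3 rose (median −0.42), and 25 of the 33 modification enzymes fell and 6 rose (median −1.19). As they stand, the medians of the synthetases and of the enzymes were 0.84 and 0.065 with median centring, and both were also above 0 with no normalization. Camera, adjusted over the 5 lists of this part, gave an adjusted p = 7.74e-06 for both; with an estimated correlation both had an adjusted p = 0.440.

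In a scan of 68 families of at least 15 genes that share a symbol prefix, camera called 7 at the preset correlation and none with an estimated correlation, where each of the 7 had an adjusted p = 0.974. Mitochondrial ribosomal protein genes of the large subunit (MRPL) were lower, with 31 of 50 falling and 9 rising (median −0.69, adjusted p = 0.00109), and so were those of the small subunit (MRPS, 20 of 28 falling, median −0.53, adjusted p = 0.00438; adjusted p = 0.974 for both with an estimated correlation), opposite to the list of cytosolic ribosomal proteins. With shift-corrected median centring this was weaker: for MRPL 23 fell and 18 rose (median −0.19), and for MRPS 10 fell and 9 rose (median 0.0058). The DDX helicase genes (22 of 33 falling, adjusted p = 0.00181; adjusted p = 0.974 with an estimated correlation) and the RBM genes (18 of 30 falling, adjusted p = 0.0425; adjusted p = 0.974) were also lower; with shift-corrected median centring 19 DDX genes fell and 9 rose, and 17 RBM genes fell and 9 rose. The intraflagellar transport genes (IFT), known from cilia, were higher, with 12 of 17 rising and none falling (median 0.76, adjusted p = 0.00449; adjusted p = 0.974 with an estimated correlation; 11 rising and 4 falling, median 0.55, with shift-corrected median centring), among them IFT80 (2.85 ± 0.09; farthest probe 0.68) and IFT20 (2.21 ± 0.27). The RPL prefix (55 of 60 rising, 4 falling, adjusted p = 2.45e-10) and the RPS prefix (38 of 42 rising, 4 falling, adjusted p = 3.84e-07) made up the rest. The RPL genes that fell were the paralogs RPL22L1, RPL26L1, RPL39L and RPL7L1, and the RPS genes that fell were RPS19BP1 and the kinase genes RPS6KA1, RPS6KA4 and RPS6KB2. As they stand, the medians of MRPL, MRPS, DDX and RBM were 1.07, 1.26, 0.63 and 0.84 with median centring and 2.21, 2.40, 1.76 and 1.97 with no normalization, and those of IFT, RPL and RPS were −0.77, −0.36 and −0.48 when shifted to the spike-in RNAs. Host genes of small nucleolar RNAs were split, with 6 of 12 rising and 6 falling, from GAS5 (3.35 ± 0.13) to SNHG17 (−1.81 ± 0.18).

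The opposite changes of ribosomal protein and ribosome biogenesis mRNAs were set against 3 explanations. A bias of bright spots was weighed with 10000 random lists matched on signal: the ribosomal protein median of 1.18 lay above 99.6% of them, but their own median was 0.56, so brightness may account for part of the rise and does not reach all of it. A general loss of newly made RNA, which would leave long-lived mRNAs, needs short-lived mRNAs to be lower than other mRNAs, but 31 of 42 immediate-early and AU-rich mRNAs rose and 7 fell, with a median of 0.83 (standard error range 0.56 to 1.11). This list includes SGK1, JUN, BTG2, EGR2, MCL1 and TNFAIP3, already named for their increase, and MYC, named for its decrease. Without them, 25 of 35 rose and 6 fell, with a median of 0.72 (0.49 to 0.96), and with shift-corrected median centring the median of these 35 was 0.87 (0.57 to 1.18). Shifted to the spike-in RNAs, 25 of the 35 fell and 4 rose (median −0.81, −1.04 to −0.58), but all genes moved by −1.53 there, so the median of these mRNAs still lay above that of all genes. Of the 42, 30 were above background in both conditions, and of these 23 rose and 6 fell (median 0.89, 0.52 to 1.25). These mRNAs as a set were thus not lower than other genes. Immediate-early genes can also be induced, which could hide such a loss, so this list cannot decide for or against it. Whether all mRNAs fell in amount is not decided. A shared response of mRNAs that begin with a 5' TOP motif stays open: 15 of 19 such mRNAs for other translation proteins rose, among them TPT1 (2.66 ± 0.04) and EIF3E (2.23 ± 0.13, farthest probe 0.64), but their median of 0.68 lay above only 79.28% of matched random lists. Camera, which does not match on signal, called this list higher (adjusted p = 0.00151, and adjusted p = 0.440 with an estimated correlation). The median of the list depended on the scaling: it was 0.29 with the Feature Extraction log ratio (11 rising, 4 falling), 1.79 with shift-corrected median centring (18 rising, none falling) and −0.86 when shifted to the spike-in RNAs. The bound below which this list would have excluded the explanation, 50%, was set after that value was seen; under the bound first set, 95%, the value would have counted against the explanation, and the treatment itself was not tested apart from dye.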
